A study of Mus musculus with 6 samples.

How the data were processed

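Lung cells of wild-type mice treated with HDM or PBS were digested, stained and sorted, and CD45+ CD4+ cells negative for CD11b and for the macrophage protein encoded by Adgre1 were collected, per the labels' protocols. Their RNA was extracted with Trizol, labelled with biotin by a whole-transcript kit and hybridised to Affymetrix mouse gene arrays. The 6 samples formed 2 groups of 3 arrays, which the titles number 1 to 3 as biological replicates within each group. Doses, days of treatment, scan dates and the number of mice per sample were not given in the sources used here, so no batch could be tested.

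The deposited table held log2 signals per probe set made by the authors with RMA (background correction, quantile normalization between arrays and a summary per probe set), per the submitters' processing notes, which name RMA without a version. The values lay between 2.95 and 14.1 and the array medians were 6.57, 6.57 and 6.62 for PBS replicates 1, 2 and 3 and 6.58, 6.61 and 6.64 for the HDM replicates. Neither a detection call nor a filter on dim probe sets was given in the sources used here. RMA makes array distributions nearly equal, so a change in the total RNA per cell cannot be seen, and values are on a relative scale. The arrays were compared for duplicates, and any 2 of them shared at most 5 exactly identical values over the 22180 genes tested.

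Probe sets were named through the platform's gene annotation. Of 33960 probe sets, 23521 had exactly 1 gene symbol, 1814 had several and 8625 had none here. Those with exactly 1 symbol gave 22180 genes, and for the 1082 genes with more than 1 probe set the one with the highest mean over all 6 arrays was used. No gene was filtered for low signal. Some genes of the lists below were not analysed here.

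Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with an intensity trend), as HDM minus PBS, two-sided, with Benjamini-Hochberg adjustment over the 22180 genes and a threshold of 0.05. Fold changes, SEs and adjusted p-values in the text come from this fit unless another is named, and SEs use limma's moderated spread. The 30 gene lists were written from general knowledge before the data were examined, together with the tests, the alternatives and the rule for naming genes. They cover T cell states, T cell identity, cell processes, handling and RNA quality, and markers of other cells that the gate could hold. Their shifts were tested with limma's camera (preset inter-gene correlation 0.01, intensity trend, Benjamini-Hochberg over the 30 lists), and again with the correlation estimated per list and with fry, which tests whether a list's genes move one way on balance. The 3 lists lower by camera and the 15 higher by it fell to 0 and 2 with the estimated correlation, the 2 being activation and tissue residency. That setting also uses far fewer degrees of freedom than the preset one, so the drop does not measure correlation between members alone. The residency list, with an estimated correlation of −0.0058, went from an unadjusted camera p of 5.66e-13 to 0.00161. Members were also counted after adjustment over the list alone.

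The naming rule took 12 genes per direction with the largest fold change among genes that passed and whose HDM and PBS values did not overlap, leaving out predicted genes, small RNAs, immunoglobulin and T cell receptor segments and olfactory or vomeronasal receptors. It further took up to 4 passing members of each list with the largest change, or the 2 largest where no member passed, and always Cd4, Ptprc, Itgam, Adgre1, Il4, Il5, Il13, Ifng, Il17a, Foxp3 and Gata3. It named 90 genes, of which 69 passed.

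The labels do not say what the replicate numbers stand for. The deviations of same-numbered arrays from their group means correlated across genes at 0.43 for the arrays numbered 1, 0.17 for those numbered 2 and 0.53 for those numbered 3, each above the minimum of 0.1 set for treating the numbers as pairs, so values with the replicate number as a block are given where they change a call or move a count by more than 1.5 times. Across numbers, PBS replicate 1 and HDM replicate 2 correlated too, at 0.25. With 3 arrays per group, a deviation shared by the arrays numbered 3 also enters the deviations of the others through the group means, and the pairing rests on the data and not on the labels.

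Alternatives were a filter on dim genes at the 25th percentile or the median, repeated quantile normalization, centring on array medians, other variance models, array weights, averaged or all probe sets, the replicate block, other thresholds and leaving out each array. Leaving out both arrays numbered 3, and joining the block with the estimated correlation, were added after seeing the data. The gene test was run on simulated data for HDM against PBS with 22180 genes, of which 200 were changed, in 10 runs. Without a block or a pair effect it recovered 28.2% of genes changed by a log2 of 0.5, 79% at 1, 94.4% at 2 and 99.4% at 3, with 3.87% false calls. With a simulated pair effect, the fit without a block recovered 5.6%, 68.6%, 97.2% and 99.6%, with 1.16% false calls, and the block fit recovered 9.8%, 66.2%, 90.6% and 97.8%, with 2.06% false calls. The list test called a list shifted by 0.5 in 10 of 10 runs and on average 0.5 other lists per run. That average left out the residency, innate lymphoid cell and chemokine receptor lists, which share genes with the shifted list. The genes were simulated independently, whereas the endothelial and stromal list, for example, had an estimated correlation of 0.84. The simulation therefore does not show how many false list calls to expect in these arrays.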

Results

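Gene expression was measured in CD4 T cells of the lung from wild-type mice that were treated with house dust mite (HDM), an allergen used to provoke allergic airway inflammation, or with PBS, the saline vehicle. The cells were sorted from digested lung as CD45+ CD4+ cells that lacked CD11b, a surface protein of myeloid cells, and the macrophage surface protein encoded by Adgre1. Their RNA was hybridised to whole-transcript Affymetrix mouse gene arrays, 3 for HDM and 3 for PBS, 1 array per sample. The samples were titled as biological replicates, and how many mice stood behind each was not stated in the labels, so the p-values measure the spread between these samples. The median signal of an array lay between 6.57 and 6.64 on the log2 scale, and 22180 genes were tested. The small number of arrays limits the precision of each value.

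The comparison of HDM with PBS asked which transcripts differed in lung CD4 T cells after allergen treatment. Cytokine genes of type 2 immunity rose: Il13, a cytokine of T helper 2 (Th2) cells that acts on the airway epithelium, was 10.2-fold higher in HDM arrays (log2 fold change 3.35 ± 0.32 SE, n = 3 per group, adjusted p = 0.00274), and Il5, the cytokine that supports eosinophils, was 4.58-fold higher (2.19 ± 0.26, adjusted p = 0.00553). Il10, an anti-inflammatory cytokine, rose 9.65-fold (3.27 ± 0.15, adjusted p = 0.000178) and Il17a, the signature cytokine of Th17 cells, rose 3.57-fold (1.84 ± 0.21, adjusted p = 0.00482). Ifng, the signature cytokine of Th1 cells, did not pass the test (log2 fold change −0.12 ± 0.33, adjusted p = 0.907). Bach2, a repressor of effector differentiation that naive T cells express, fell (−0.97 ± 0.11, adjusted p = 0.00474). The plot of selected genes gives their signal in each array.

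**Figure D1:**
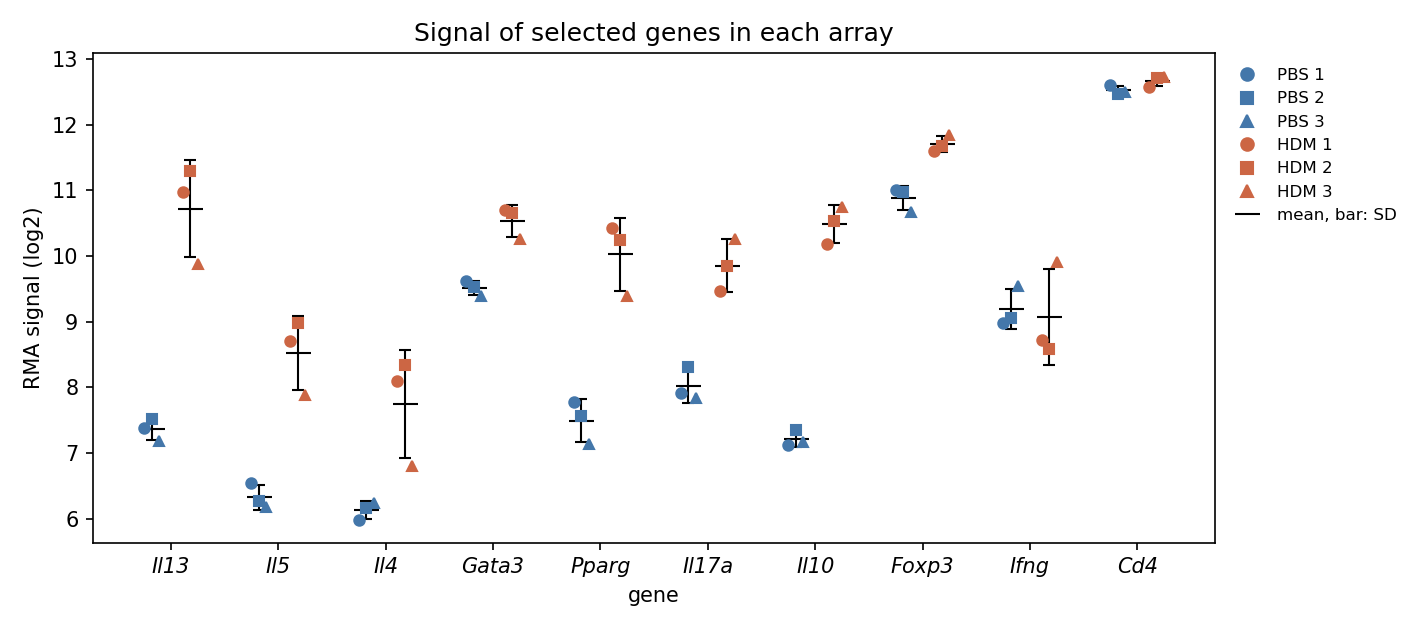
RMA signal (log2, vertical axis) of 10 genes in the 3 PBS arrays (blue) and the 3 HDM arrays (orange), with marker shape giving the replicate number, horizontal ticks the group mean and bars the SD. Il13 lay at 7.37 ± 0.17 (SD, n = 3) in PBS and 10.72 ± 0.74 in HDM, whereas Cd4 lay at 12.52 ± 0.07 and 12.67 ± 0.08.

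In total, 531 genes were higher and 345 were lower in HDM, with limma at an adjusted p below 0.05. At least a 2-fold difference was reached by 167 of the raised and 26 of the lowered genes, and 23 genes rose at least 4-fold. Of the 22180 genes, 5012 had their 3 HDM values on one side of the 3 PBS values, a separation that chance gives to 10% of genes; these included all 876 called genes, which the test chose on the same arrays. With the replicate number as a block, 1319 genes were higher and 1334 lower, and these included all 531 and all 345. With adjustment over all probe sets, 352 of the genes were higher and 191 lower. The counts also moved with single arrays: they were 192 higher and 65 lower without PBS replicate 1, 202 and 70 without HDM replicate 1, 177 and 41 without PBS replicate 2, 181 and 55 without HDM replicate 2, and 845 and 722 without HDM replicate 3.

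The 12 raised genes named for the size of their change held several with known roles in allergic inflammation or tissue T cells. Retnla, a secreted protein induced by type 2 cytokines, was 14.5-fold higher (3.85 ± 0.65, adjusted p = 0.0192). Fgl2, an effector molecule of regulatory T cells, rose 7.59-fold (2.92 ± 0.17, adjusted p = 0.00047), and Mmp12, the macrophage elastase, rose 6.01-fold (2.59 ± 0.54, adjusted p = 0.0414). Pparg, a nuclear receptor that supports Th2 effector function, rose 5.77-fold, Cxcr6, a chemokine receptor of tissue T cells, 5.69-fold, and Itgae, which encodes the CD103 integrin chain, 5.67-fold. Vdr, the vitamin D receptor, rose by 2.40 on the log2 scale, Adam8, a membrane metalloprotease, by 2.37, Ly6g5b by 2.34 and Apol9b by 2.30. Retnla and Mmp12 lost the call when any array other than HDM replicate 3 was left out, with adjusted p of up to 0.0919 and 0.164.

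The 12 lowered genes named by the same rule changed less. Gbp11, a guanylate-binding protein of the interferon-inducible family, fell by 1.64 on the log2 scale (SE 0.15, adjusted p = 0.00261), and Gzma, the protease granzyme A of cytotoxic granules, fell by 1.63 (SE 0.19, adjusted p = 0.00524). Zbtb10, Rras2, Tubb2a, Cnn3, Slc28a2b, Arhgap29, Klrd1, Rab3ip, Trim13 and Nedd4l fell by between 1.11 (Nedd4l) and 1.49 (Zbtb10). Zbtb10, Rras2, Tubb2a, Cnn3 and Klrd1 lost the call when any array other than HDM replicate 3 was left out (adjusted p of up to 0.128, 0.122, 0.204, 0.192 and 0.128). Trim13 lost it without HDM replicate 1 or either replicate 2 (adjusted p of up to 0.0947), and Rab3ip without either replicate 2 (up to 0.0659).

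Of 16 measured genes of the Th2 list, 10 rose and 6 did not pass, and 12 rose and 1 fell when adjusted over the list alone. With the replicate block 10 rose and 1 fell, Bhlhe41 (−0.53 ± 0.20, adjusted p = 0.211, 0.03 with the block), which lay outside the naming rule and was picked after its values were seen. Beside Il13, Il5 and Pparg these included Ccr8, a chemokine receptor of Th2 and regulatory T cells (2.25 ± 0.27, adjusted p = 0.00593), Il17rb, a subunit of the interleukin 25 receptor (2.20 ± 0.43, adjusted p = 0.0335), and Gata3, the Th2 master transcription factor (1.02 ± 0.13, adjusted p = 0.00722). A second, dimmer probe set of Gata3 differed by only 0.31, and the mean of both by 0.67 (adjusted p = 0.0154). The list's median log2 fold change was 1.30 (camera adjusted p = 8.15e-12), and adjusted p = 0.0583 with an estimated correlation. Its median difference was 1.74 between the arrays numbered 1, 1.48 between those numbered 2 and 1.09 between those numbered 3. Il4, the founding Th2 cytokine, rose 3.07-fold (1.62 ± 0.35, adjusted p = 0.0489), with differences of 2.12, 2.17 and 0.56 in these pairs. Il4 and Il17rb lost the call when any array other than HDM replicate 3 was left out (adjusted p of up to 0.179 and 0.139), and Il4 also under 6 other planned settings, with adjusted p between 0.0501 (averaged probe sets) and 0.0817 (all probe sets).

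Of 18 measured genes of regulatory T cells, 8 rose and 10 did not pass, 13 rose when adjusted over the list alone, and 14 rose with the replicate block. Foxp3, the lineage transcription factor, rose 1.77-fold (0.83 ± 0.11, adjusted p = 0.00851), Il2ra, the interleukin 2 receptor alpha chain, 2.24-fold, and Klrg1, a receptor of terminally differentiated effector cells, 2.30-fold. The median log2 fold change was 0.81 (camera adjusted p = 5.17e-12), and adjusted p = 0.0583 with an estimated correlation. Of the 18 genes, 7 were also in another list, Itgae among them in the tissue residency list. Without both arrays numbered 3, 13 of the 18 rose and 2 fell. Klrg1 lost the call without either array numbered 1 or without HDM replicate 2 (adjusted p of up to 0.0602).

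Among 11 measured Th17 genes, 4 rose: Il17a, Ahr, a ligand-activated transcription factor (1.28 ± 0.11, adjusted p = 0.00249), Il1r1, the interleukin 1 receptor (1.16 ± 0.17, adjusted p = 0.0111), and Ccr6, a chemokine receptor (1.01 ± 0.17, adjusted p = 0.0213). When adjusted over the list alone 8 rose, as 8 did with the replicate block. The list median was 0.71 (camera adjusted p = 1.07e-07), and adjusted p = 0.144 with an estimated correlation, and the median was 0.47 without both arrays numbered 3. Il1r1 lost the call without HDM replicate 2 (adjusted p = 0.0602), and Ccr6 without either array numbered 1 or without HDM replicate 2 (up to 0.0998).

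Of 13 measured genes of T follicular helper cells, 5 rose, 1 fell and 7 did not pass. Pdcd1, the inhibitory receptor PD-1, rose 4.23-fold (2.08 ± 0.26, adjusted p = 0.00705), Maf, a transcription factor for Il10 and Il21, 2.96-fold (1.57 ± 0.08, adjusted p = 0.000281), Il21, a cytokine that helps B cells, 2.61-fold (1.38 ± 0.27, adjusted p = 0.033), and Tox2, a transcription factor, 1.84-fold. The fifth was Icos, a costimulatory receptor (0.60), and the lowered gene was Slamf6, a receptor of less differentiated T cells (−0.42); the naming rule did not choose either, and they were picked after their values were seen. When adjusted over the list alone 6 rose and 1 fell, and with the replicate block 8 rose and 2 fell. The median was 0.49 (camera adjusted p = 0.000188), and adjusted p = 0.18 with an estimated correlation. Il21 lost the call when any array other than HDM replicate 3 was left out (adjusted p of up to 0.122), and Tox2 without either replicate 2 (up to 0.0669).

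Coinhibitory receptors and related genes followed a like count: 5 of 12 rose and 7 did not pass. Havcr2, the receptor TIM-3, rose 3.55-fold (1.83 ± 0.32, adjusted p = 0.0224), Lag3, an inhibitory receptor for MHC class II, 3.01-fold (1.59 ± 0.15, adjusted p = 0.00274), and Nt5e, the ectonucleotidase CD73, 1.98-fold (0.99 ± 0.09, adjusted p = 0.00245). The others were Pdcd1 and, outside the naming rule, Pdcd1lg2 (0.79), the PD-1 ligand PD-L2. When adjusted over the list alone 8 rose and 1 fell, as 8 and 1 did with the replicate block. The median was 0.79 (camera adjusted p = 2.31e-06), and adjusted p = 0.0858 with an estimated correlation. Havcr2 lost the call without PBS replicate 1 or without either replicate 2 (adjusted p of up to 0.112).

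Of 15 measured genes of naive and recirculating T cells, 12 fell and 3 did not pass, all 15 fell when adjusted over the list alone, and 14 fell with the replicate block. The median was −0.85 (camera adjusted p = 4.98e-18), and adjusted p = 0.0583 with an estimated correlation. Dapl1 fell by 1.01 (SE 0.12), Bach2 by 0.97 (SE 0.11), and Igfbp4 and Actn1 by 0.94 each (SE 0.10). Of 23 activation genes, 10 rose, 20 when adjusted over the list alone, 19 with the replicate block, and 17 without both arrays numbered 3. They included S100a6 (1.38 ± 0.13) and S100a4 (1.23 ± 0.10), calcium-binding proteins, Cd44, the adhesion receptor that marks antigen-experienced T cells (1.15 ± 0.10), and Tnfsf11, the cytokine RANKL (1.15 ± 0.17). Tnfsf11 lost the call without either HDM replicate 1 or HDM replicate 2 (adjusted p of up to 0.0621).

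Of 12 measured genes of tissue residency, 7 rose, 10 when adjusted over the list alone and 8 with the block. Cxcr6, Itgae and Ccr8 led them, followed by P2rx7, a receptor for extracellular ATP (1.05 ± 0.22, adjusted p = 0.0436), which lost the call when any array other than HDM replicate 3 was left out (adjusted p of up to 0.170). The activation list (median 0.65, camera adjusted p = 2.62e-17) and the residency list (median 0.80, camera adjusted p = 5.17e-12) were the lists whose call held with an estimated correlation (adjusted p = 0.0313 for each). Neither held with the replicate block and an estimated correlation together (adjusted p = 0.215 for each), a setting chosen after seeing the data in which no list passed. With 6 arrays that setting leaves very few residual degrees of freedom, and the Th2 list had the same adjusted p there. It could hardly pass any list, so it does not decide whether the 2 calls hold.

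**Figure D2:**
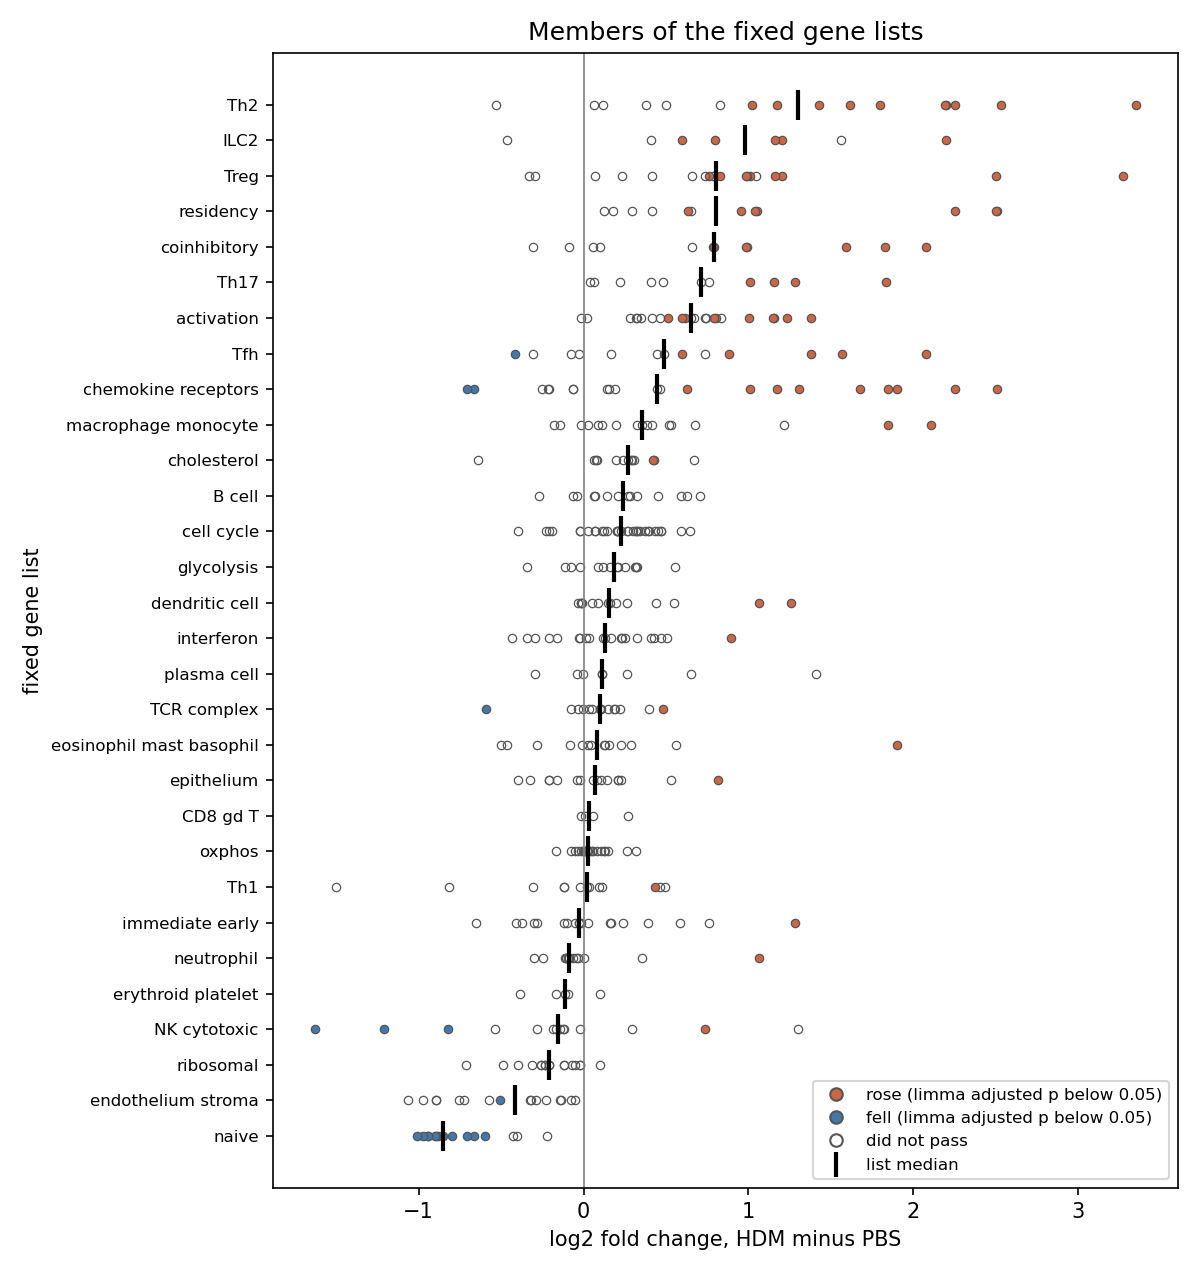
Log2 fold change of HDM over PBS (horizontal axis) of each measured member of the 30 gene lists (vertical axis), with filled circles for genes that rose (orange) or fell (blue) at a limma adjusted p below 0.05, open circles for genes that did not pass and black ticks for list medians. The medians run from −0.85 for the naive list to 1.30 for the Th2 list.

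Among 21 chemokine receptors and related trafficking genes, 9 rose and 2 fell, the same numbers as when adjusted over the list alone, and 11 rose and 2 fell with the block. Ccr3, the eotaxin receptor, rose 3.74-fold (1.90 ± 0.18, adjusted p = 0.00274), and Ccr2, a receptor of effector T cells and monocytes, 3.60-fold (1.85 ± 0.09, adjusted p = 0.000178). The 2 lowered genes, S1pr1 (−0.70) and Ccr7 (−0.66), which guide T cells out of and into lymph nodes, fell outside the naming rule and were also members of the naive list. The list median was 0.44 (camera adjusted p = 9.32e-06), with adjusted p = 0.0583 with an estimated correlation, and 0.26 without HDM replicate 3. Of the 21 genes, 11 were in another list too.

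The Th1 list did not pass. Of its 13 measured genes, 1 rose, Il18r1, the interleukin 18 receptor (0.43 ± 0.09, adjusted p = 0.0379), and 12 did not pass, and 1 rose and 1 fell when adjusted over the list alone. With the replicate block 2 rose, Il18r1 and Cxcr3 (0.46 ± 0.19, adjusted p = 0.263, 0.0118 with the block), and 2 fell. The lowered genes were Il12rb2 (−1.50 ± 0.76, adjusted p = 0.364, 0.000396 with the block) and Ccl5 (−0.82 ± 0.20, adjusted p = 0.071, 0.00276 with the block). Cxcr3, Il12rb2 and Ccl5 lay outside the naming rule and were picked after their values were seen. The list's median was 0.02 and its mean −0.09, and the test pointed up (camera adjusted p = 0.814). Ifng differed by −0.26, −0.47 and 0.37 in the pairs of arrays numbered 1, 2 and 3, and without both arrays numbered 3 its difference of −0.36 passed (adjusted p = 0.0491). Il18r1 lost the call when any array other than HDM replicate 3 was left out (adjusted p of up to 0.164).

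Of 14 measured genes of natural killer and cytotoxic cells, 3 fell, 1 rose and 10 did not pass. Beside Gzma, Klrd1, the lectin receptor CD94, fell by 1.21 (SE 0.23, adjusted p = 0.0317) and Prf1, the pore-forming perforin, by 0.82 (SE 0.16, adjusted p = 0.0308), while Ctsw, a cathepsin of cytotoxic lymphocytes, rose by 0.73 (SE 0.10, adjusted p = 0.00929). When adjusted over the list alone 4 fell and 3 rose, and with the replicate block 4 fell and 2 rose. The list median of −0.15 did not pass (camera adjusted p = 0.141), but did without HDM replicate 3 (−0.26, adjusted p = 0.0142) and without both arrays numbered 3 (−0.09, adjusted p = 0.0475), and it was −0.05 without PBS replicate 3. Klrd1 and Prf1 lost the call when any array other than HDM replicate 3 was left out (adjusted p of up to 0.128 and 0.133), and Ctsw without either replicate 2 (up to 0.0597). The 4 measured genes of CD8 and gamma delta T cells, among them Cd8a (0.06 ± 0.20) and Blk (0.27 ± 0.31), gave 0 calls with limma, 0 with the replicate block, 0 when adjusted over the list alone and 0 at an unadjusted p below 0.05 (list median 0.03, camera adjusted p = 0.768). The list's gamma delta receptor genes Trdc, Tcrg-C1, Tcrg-C2 and Tcrg-C4 were not analysed here, so these counts say little of gamma delta T cells.

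The genes of the sort gate did not pass. Cd4 differed by 0.15 (SE 0.07, adjusted p = 0.294), Ptprc, which encodes CD45, by −0.07 (SE 0.07, adjusted p = 0.655), Itgam, which encodes CD11b, by −0.02 (SE 0.23, adjusted p = 0.984) and Adgre1 by 0.39 (SE 0.24, adjusted p = 0.469). Without 1 array the difference ranged from 0.16 to 0.62 for Adgre1 and from −0.12 to −0.03 for Ptprc. Of 15 measured genes of the T cell receptor complex and its signalling, Zap70, a proximal kinase, rose (0.48 ± 0.10, adjusted p = 0.045) and Trat1, a transmembrane adaptor, fell (−0.59 ± 0.08, adjusted p = 0.00722). When adjusted over the list alone, and with the replicate block, 4 rose and 1 fell. The list median of 0.10 did not pass (camera adjusted p = 0.0572), but did with the block (0.0302), with repeated quantile normalization (median 0.12, adjusted p = 0.0114), without PBS replicate 1 (0.0218) and without HDM replicate 1 (0.044), and it ranged from 0.06 to 0.15 without 1 array. Zap70 lost the call when any array other than HDM replicate 3 was left out (adjusted p of up to 0.203).

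Of 33 measured cell cycle genes, 0 passed with limma over all genes and 0 when adjusted over the list alone, while 8 were higher and 3 lower at an unadjusted p below 0.05 and, with the replicate block, 10 rose and 1 fell. The members with the largest differences were Mki67, the proliferation marker Ki-67 (0.64 ± 0.23, adjusted p = 0.187, 0.00412 with the block), and Top2a, a topoisomerase of dividing cells (0.59 ± 0.18, adjusted p = 0.134, 0.0107 with the block), and Top2a also passed without PBS replicate 3 (adjusted p = 0.0379). The list as a whole was higher (median 0.23, camera adjusted p = 0.00241), with adjusted p = 0.629 with an estimated correlation and 0.399 without HDM replicate 3 (median 0.06), while the median was 0.36 without HDM replicate 1 and 0.15 without PBS replicate 2. Immediate early and heat shock genes, which respond to stimulation and handling, had a median of −0.02, a mean of 0.07 and an upward test that did not pass (camera adjusted p = 0.464). Of 19 such genes 1 rose, Egr3 (1.28 ± 0.22, adjusted p = 0.0198), 2 rose and 1 fell when adjusted over the list alone, and 4 rose and 2 fell with the block. Egr3 lost the call without any 1 array numbered 1 or 2 (adjusted p of up to 0.0845).

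The metabolic and interferon lists held few genes that passed. Of 13 measured genes of cholesterol synthesis 1 rose, Nsdhl (0.42 ± 0.09, adjusted p = 0.0418), 2 when adjusted over the list alone, and with the block 4 rose and 1 fell (median 0.27, camera adjusted p = 0.000739, and adjusted p = 0.0858 with an estimated correlation). Nsdhl lost the call when any array other than PBS replicate 3 was left out (adjusted p of up to 0.179). Of 14 glycolysis genes 0 passed with limma, 4 were higher and 1 lower at an unadjusted p below 0.05, 2 rose when adjusted over the list alone, and with the block 4 rose and 1 fell. Tpi1 (0.55 ± 0.14, adjusted p = 0.071, 0.00527 with the block) and Slc2a1, the glucose transporter GLUT1 (−0.34 ± 0.12, adjusted p = 0.171, 0.0436 with the block, and −0.19 with averaged probe sets), differed most among them. Without single arrays, Tpi1 passed without PBS replicate 3 (adjusted p = 0.0272) and Slc2a1 without HDM replicate 3 (0.0466). The glycolysis median of 0.18 passed (camera adjusted p = 0.0208), but not without PBS replicate 1 (0.0926), not without HDM replicate 3 (0.0917), and adjusted p = 0.154 with an estimated correlation. Of 21 interferon-induced genes 1 rose, Isg20, an exonuclease (0.89 ± 0.15, adjusted p = 0.0209), 3 when adjusted over the list alone and 5 with the block. The interferon median of 0.13 passed (camera adjusted p = 0.0459), with adjusted p = 0.629 with an estimated correlation, 0.0808 with the block, 0.174 for genes at or above the median signal (median 0.08), and 0.114, 0.202, 0.164 and 0.135 without PBS replicate 2, HDM replicate 2, PBS replicate 3 and HDM replicate 3. The median was 0.0042 without HDM replicate 2, 0.05 without PBS replicate 3, 0.20 without PBS replicate 1, 0.24 without HDM replicate 1 and 0.08 without both arrays numbered 3. Isg20 lost the call without any of the PBS arrays or without HDM replicate 2 (adjusted p of up to 0.0985).

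Ribosomal protein genes were lower as a list (17 measured, median −0.21, camera adjusted p = 0.000172, and adjusted p = 0.232 with an estimated correlation). With limma 0 of them passed, as when adjusted over the list alone, 9 were lower at an unadjusted p below 0.05, and 5 fell with the block. Rpl3 (−0.71 ± 0.26, adjusted p = 0.194, 0.0384 with the block) and Rpl6 (−0.49 ± 0.13, adjusted p = 0.086, 0.0244 with the block) differed most, and Rpl3 passed without PBS replicate 3 (adjusted p = 0.0182), and of the other probe sets of Rpl3 one nearly as bright differed by −0.56 and a dimmer one by −0.09, and the mean of the 3 by −0.45. Of 21 oxidative phosphorylation genes 0 passed with limma and 0 when adjusted over the list alone, 2 were higher at an unadjusted p below 0.05 and 1 rose with the block, Ndufa1 (0.32 ± 0.09, adjusted p = 0.113, 0.0459 with the block). Ndufb9, the member with the next largest difference, lay at 0.27 ± 0.11, and the list median at 0.02 (camera adjusted p = 0.229).

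Markers of other cells that the gate could hold were also measured. Of 17 macrophage and monocyte genes, 2 rose, Ccr2 and Chil3, a chitinase-like protein of alternatively activated macrophages (2.11 ± 0.38, adjusted p = 0.0248), and 15 did not pass; 3 rose when adjusted over the list alone, and 6 with the block or without both arrays numbered 3. The list median was 0.36 (camera adjusted p = 0.000238), and adjusted p = 0.154 with an estimated correlation. These values stood beside the rise of Retnla and Mmp12, in cells gated as negative for CD11b and the Adgre1 protein. Of 14 dendritic cell genes, 2 rose, Ccl17, a chemokine for Ccr4-bearing cells (1.26 ± 0.11, adjusted p = 0.00249), and Itgax, which encodes CD11c (1.06 ± 0.22, adjusted p = 0.038), 2 also when adjusted over the list alone, and 4 with the block. Their median of 0.15 passed (camera adjusted p = 0.00786), but not without PBS replicate 1 (0.0528), not without HDM replicate 3 (0.208), and adjusted p = 0.288 with an estimated correlation. That median was 0.26 without HDM replicate 1 and 0.10 without PBS replicate 2. Chil3 lost the call without any 1 array numbered 1 or 2 (adjusted p of up to 0.110), and Itgax without any PBS array or HDM replicate 2 (up to 0.132).

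Granulocyte markers showed single raised genes. Of 14 neutrophil genes 1 rose, Mmp9, a gelatinase (1.06 ± 0.11, adjusted p = 0.0041), and of 14 eosinophil, mast cell and basophil genes 1 rose, Ccr3, with 1 in each when adjusted over the list alone; with the block, 1 neutrophil gene rose, and 2 of the other list rose and 1 fell. The neutrophil list had a median of −0.09, a mean of 0.01 and an upward test that did not pass (camera adjusted p = 0.874), and its median was 0.21 and passed without PBS replicate 3 (adjusted p = 0.00997). The median of the eosinophil, mast cell and basophil list, 0.08, did not pass (camera adjusted p = 0.248), and it was 0.03 without HDM replicate 3 (adjusted p = 0.716) and 0.29 for genes at or above the median signal (adjusted p = 0.476). Of 8 measured genes of group 2 innate lymphoid cells, 5 rose, 7 when adjusted over the list alone, and 7 rose and 1 fell with the block (median 0.98, camera adjusted p = 9.49e-07, and adjusted p = 0.0583 with an estimated correlation). The 5 were Il17rb, Klrg1, Il2ra, Hpgds, a prostaglandin D synthase (0.80 ± 0.16, adjusted p = 0.0375), and, outside the naming rule, Icos, and the gene that fell with the block was Kit (−0.47, adjusted p = 0.0455 with the block), also picked after its values were seen; T cells also express Il2ra and Icos, and 6 of the 8 genes were in another list. Hpgds, like Il17rb, lost the call when any array other than HDM replicate 3 was left out (adjusted p of up to 0.135 and 0.139), and Klrg1 without either array numbered 1 or without HDM replicate 2 (up to 0.0602).

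Of 14 measured B cell genes, 0 passed with limma, 0 when adjusted over the list alone and 0 at an unadjusted p below 0.05, while 3 rose with the replicate block. The MHC class II genes H2-Ab1 (0.71 ± 0.41, adjusted p = 0.438, 0.00831 with the block) and H2-Eb1 (0.63 ± 0.33, adjusted p = 0.387, 0.0183 with the block) differed most, with ranges of 0.31 to 1.09 and 0.27 to 0.89 without 1 array. The B cell median of 0.24 did not pass (camera adjusted p = 0.119), but did with the block (0.00934) and without HDM replicate 1 (0.000283), HDM replicate 2 (0.049) or PBS replicate 3 (0.00898). Of 8 plasma cell genes 0 passed with limma, 2 were higher at an unadjusted p below 0.05 and 2 rose when adjusted over the list alone, and with the block 2 rose and 1 fell (median 0.11, camera adjusted p = 0.141, and 0.044 without HDM replicate 1). The plasma cell median ranged from 0.03 to 0.19 without 1 array and was 0.05 for genes at or above the median signal. The plasma cell genes were led by Jchain, the joining chain of secreted antibody (1.41 ± 0.36, adjusted p = 0.0789, 0.00235 with the block and 0.0447 without HDM replicate 3), and Prdm1, which effector T cells express too (0.65 ± 0.16, adjusted p = 0.0713, 0.022 with the block).

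Of 16 endothelial and stromal genes 1 fell, Pecam1, which encodes CD31 (−0.51 ± 0.08, adjusted p = 0.0169), 1 also when adjusted over the list alone, and 7 fell with the block. The list median was −0.42 (camera adjusted p = 0.00241), with adjusted p = 0.629 with an estimated correlation, 6.79e-07 with the block and 0.248 with the block and an estimated correlation. It lay at −0.31, −0.62 and −0.39 in the pairs of arrays numbered 1, 2 and 3. It did not pass for genes at or above the median signal (−0.31, adjusted p = 0.0815), without HDM replicate 1 (−0.27, adjusted p = 0.095) or PBS replicate 3 (−0.22, adjusted p = 0.144). Pecam1 lost the call without any 1 array numbered 1 or 2 (adjusted p of up to 0.0961). Of 16 epithelial genes 1 rose, Cdh1, which encodes E-cadherin, a ligand of CD103 (0.82 ± 0.15, adjusted p = 0.0292), 2 when adjusted over the list alone, and with the block 2 rose and 1 fell. A second, dimmer probe set of Cdh1 differed by only 0.09, the mean of both by 0.45 (adjusted p = 0.0742), and Cdh1 lost the call when any array other than HDM replicate 3 was left out (adjusted p of up to 0.113). The epithelial median of 0.07 did not pass (camera adjusted p = 0.333) but did without HDM replicate 1 (0.14, adjusted p = 0.0384). Of 5 measured erythroid and platelet genes 0 passed with limma, with the block, when adjusted over the list alone or at an unadjusted p below 0.05 (median −0.11, camera adjusted p = 0.464); Ppbp lay at −0.38 ± 0.56 and Itga2b at −0.17 ± 0.11.

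Some calls ended and others were gained under the other planned settings. With all probe sets tested together, Mmp12, Rras2, Tubb2a, Cnn3, Klrd1, Il17rb, Il18r1, Il21, P2rx7, Zap70, Nsdhl, Itgax, Prf1, Hpgds, Cdh1 and Il4 did not pass (adjusted p between 0.0512 and 0.0817). Tubb2a, Cnn3 and Il4 did not pass with repeated quantile normalization (adjusted p of up to 0.0559), P2rx7, Zap70 and Il4 with arrays centred on their median (up to 0.0681), Zap70 and Il4 without an intensity trend (up to 0.0548) and Mmp12, Tubb2a, Cnn3 and Il4 with a robust variance model (up to 0.0639). The cell cycle, interferon, ribosomal, dendritic cell and endothelial lists did not pass with fry (adjusted p of up to 0.451). Calls were gained by Top2a, Tpi1, Rpl3, Rpl6 and Jchain with array weights (limma adjusted p between 0.0189 and 0.0498). Among genes at or above the median signal, Tpi1 and Prdm1 gained the call (limma adjusted p = 0.0426 and 0.045).

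The arrays numbered 3 stood apart from the other 4 in both groups. The first principal component, with 48.8% of the variance, separated HDM from PBS, and the second, with 27.6%, placed PBS replicate 3 at 14.8 and HDM replicate 3 at 27.5, with the others between −21.5 and −2.53. Compared with the mean of the other 4 arrays, the mean of these 2 was higher by a median of 0.78 over the 16 endothelial and stromal genes, with 16 higher, by 0.73 over the 14 B cell genes, with 14 higher, and by 0.67 over the 14 neutrophil genes, with 14 higher. All 13 Th1 genes were higher too (median 0.50), and 32 of 33 cell cycle genes (0.37). Without both of these arrays, an alternative chosen after seeing the data, 1250 genes were higher and 1326 lower, among them 525 and 341 of the genes called with all 6 arrays. The Th2 list then had 11 raised genes and a median of 1.64, and the naive list 13 lowered genes and a median of −0.94. Of the coinhibitory genes 8 then rose and 1 fell, of the Th1 genes 3 rose and 3 fell, and of the cell cycle genes 5 rose and 2 fell.

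**Figure D3:**
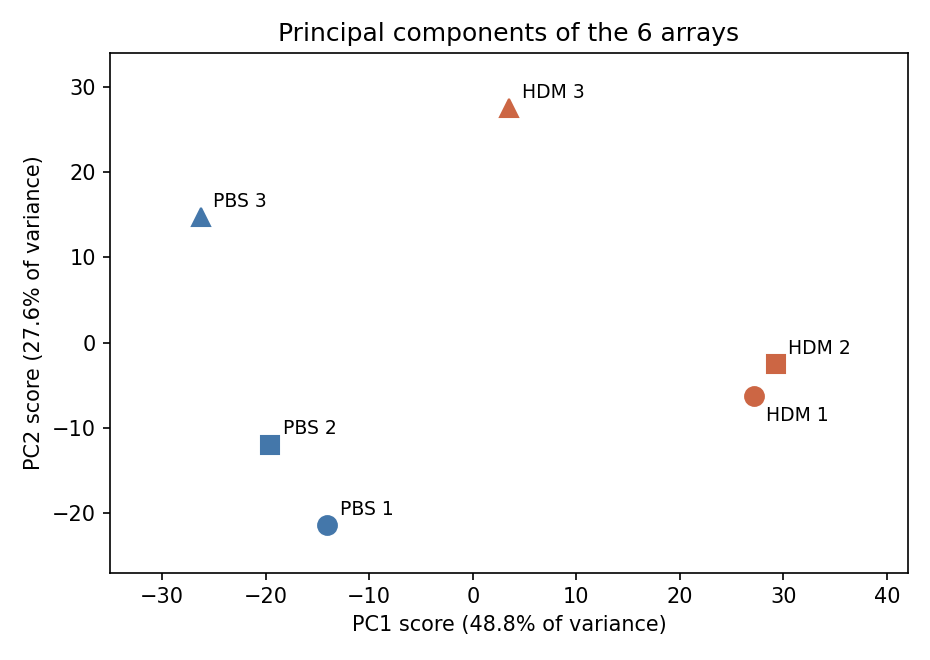
Scores of the 6 arrays on the first (horizontal axis) and second (vertical axis) principal components of all 22180 genes, with PBS in blue, HDM in orange and marker shape giving the replicate number. HDM replicate 3 lies at 3.51 on the first component and the other HDM arrays at 27.2 and 29.3, while the PBS arrays lie between −26.3 and −14.1.

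**Figure D4:**
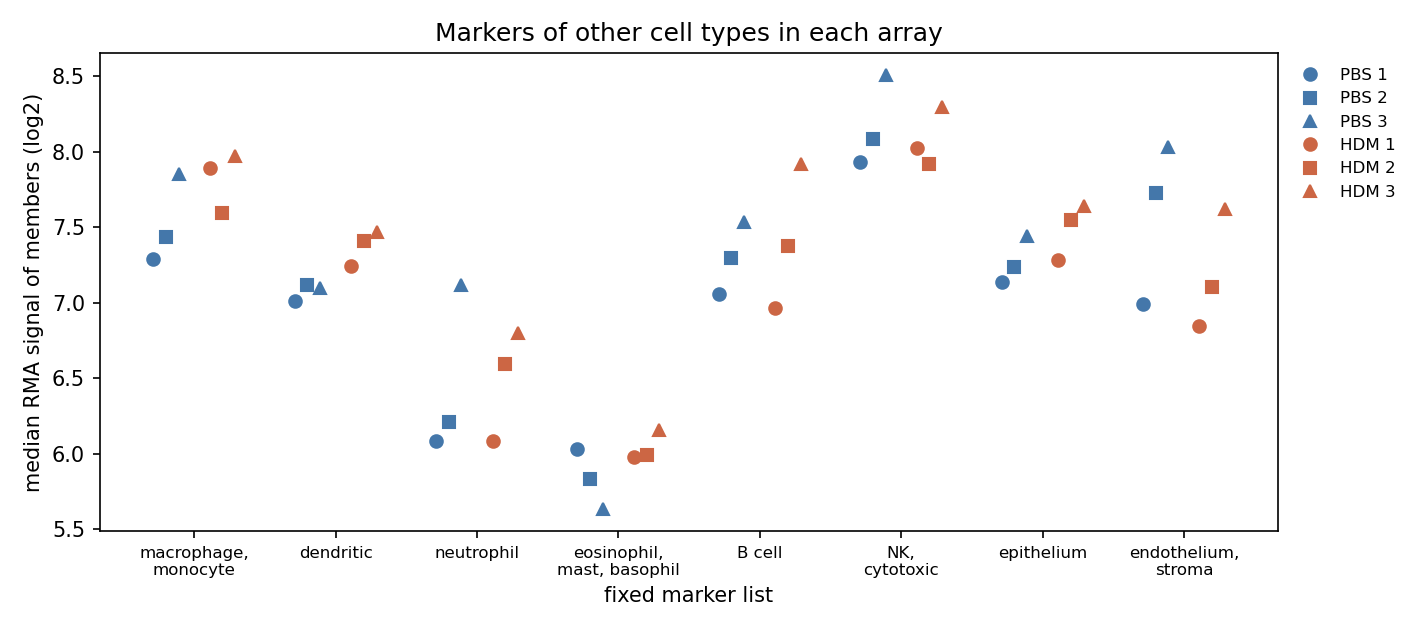
Median RMA signal (log2, vertical axis) over the measured members of 8 lists of other cell types (horizontal axis) in each PBS (blue) and HDM (orange) array, with marker shape giving the replicate number. The endothelial and stromal median was 8.03 in PBS replicate 3 and 7.62 in HDM replicate 3. It was 6.99 in PBS and 6.85 in HDM replicate 1, and 7.72 in PBS and 7.10 in HDM replicate 2.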

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

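Probe sets without a single gene symbol lay outside the gene-level comparison and were tested with all probe sets of the table by limma. Of 1814 probe sets with several gene symbols, 26 were higher and 12 lower in HDM. Of 8625 probe sets with no gene symbol here, 57 were higher and 26 lower, with log2 fold changes of up to 3.04. They were singled out because a difference from the PBS arrays appeared in data that the comparison of genes did not use, and no explanation was tested.

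Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, called as many as 876 genes, and the highest of the others called 0. So few splits cannot give a share under 0.05. The real split parted all 3 same-numbered pairs, as did 3 of the others, which called 0 genes at most.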

How the results depend on the processing

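Of the settings below, leaving out both arrays numbered 3 and joining the block with an estimated correlation were chosen after seeing the data. The number of genes higher or lower stayed within 1.5 times of 531 and 345 with a filter at the 25th percentile (604 and 471), repeated quantile normalization (524 and 361), arrays centred on their median (453 and 310), no intensity trend (534 and 342), a robust variance model (530 and 360) and averaged probe sets (509 and 328). It moved to 628 and 557 for genes at or above the median signal, 914 and 923 with array weights, 352 and 191 with adjustment over all probe sets (448 and 238 probe sets), 1319 and 1334 with the replicate block and 1250 and 1326 without both arrays numbered 3. Stricter or looser thresholds gave 172 and 55 (adjusted p 0.01), 819 and 716 (0.10) and 167 and 26 (at least a 2-fold change). Without 1 array the counts ranged from 177 to 845 higher and from 41 to 722 lower. The lists called higher and lower, 15 and 3, were 2 and 0 with an estimated correlation, 12 and 1 with fry, 0 and 0 with the block and an estimated correlation, and 11 to 19 and 2 to 4 without 1 array. Both settings with an estimated correlation use few degrees of freedom, so their counts do not measure correlation between members alone. Of 69 named genes that passed, 38 kept the call without each array in turn and 31 lost it at least once. Other planned settings ended 16 such calls (all probe sets), 4 (robust model), 3 (repeated quantile normalization), 3 (arrays centred), 2 (no trend) and 2 (averaged probe sets). The block ended no call of a named gene and ended that of the interferon list. The values that changed sign did not pass with all arrays. The Th1 list median was −0.0075 with repeated quantile normalization, −0.030 without both arrays numbered 3, and −0.12 to 0.19 without 1 array. Without both arrays numbered 3, the neutrophil list median was 0.0034, that of CD8 and gamma delta T cells −0.10 and Cd8a −0.22, and Cd8a was −0.12 with array weights. Without 1 array, the list medians ranged from −0.23 to 0.21 (neutrophil), −0.093 to 0.194 (CD8 and gamma delta T), −0.060 to 0.143 (epithelium), −0.15 to 0.12 (immediate early), −0.220 to 0.020 (erythroid and platelet), −0.0093 to 0.071 (oxidative phosphorylation) and −0.020 to 0.526 (B cell), and the log2 fold changes from −0.10 to 0.26 (Cd8a), −0.79 to 0.27 (Ppbp), −0.25 to 0.15 (Itgam), −0.54 to 0.12 (Ifng) and −0.083 to 0.63 (Blk). The cause of these changes was not tested, except that a threshold changes the counts by construction. No detection calls were used, so what low signal limits is not known.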

Other observations

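The gene families here, the comparison of the arrays numbered 3, the tests of the third pair, the check of list members by signal level and the test of macrophage RNA of unchanged makeup were chosen after the values were seen, and the 4 marker list tests after single members such as Chil3 had been seen. The Gimap genes, GTPases that support lymphocyte survival, were lower as a family: the difference was below 0 for all 8 measured genes in each of the 3 pairs, with a median log2 fold change of −0.29 (camera unadjusted p = 3.53e-07, and unadjusted p = 0.0193 with an estimated correlation). Gimap6 fell by 0.75 (SE 0.08, limma adjusted p = 0.00417) and Gimap3 by 0.63 (SE 0.10, adjusted p = 0.0167), and 4 of the 8 fell with the replicate block. Of 73 small nucleolar RNA genes, which guide chemical modification of ribosomal RNA, 3 fell (26 with the block), with a median of −0.30 (camera unadjusted p = 9.39e-12, and unadjusted p = 0.102 with an estimated correlation). Of 17 immunoglobulin variable segments 1 rose, Iglv1 (1.25 ± 0.27, adjusted p = 0.0457), and 6 rose with the block. Their median differences in the pairs of arrays numbered 1, 2 and 3 were 0.15, 0.51 and 1.36, and the family median was 0.60 (camera unadjusted p = 1.34e-05, and unadjusted p = 0.244 with an estimated correlation). Of 472 microRNA genes 3 rose and 7 fell (11 and 29 with the block), and 1 of 10 guanylate-binding protein genes fell (3 rose and 1 fell with the block). Of 53 keratin and 7 Klra genes 0 passed with limma, and with the block 2 keratin genes rose and 0 of the Klra genes passed.

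Single genes, picked after their values were seen, were higher in the arrays numbered 3 in both groups. The mean of these arrays lay above that of the other 4 arrays by 3.05 for Thbs1, a matrix glycoprotein of platelets and macrophages, 2.70 for Il1b, the cytokine interleukin 1 beta, 2.48 for Ptgs2, the inducible cyclooxygenase, 2.24 for Acod1, which makes itaconate, 1.98 for Bgn, a matrix proteoglycan, 1.59 for Cd14, a monocyte receptor, and 1.52 for Cd79a, a B cell receptor chain. Thbs1 lay at 10.35 in PBS replicate 3 and 9.97 in HDM replicate 3, and between 6.67 and 7.36 in the others.

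Retnla, Chil3 and Mmp12, which macrophages express strongly, rose in cells sorted as negative for CD11b and the Adgre1 protein. A larger share of macrophage RNA could contribute, because the interval of the macrophage and monocyte list (median 0.358, 95% bootstrap interval 0.0862 to 0.528) spans the log2 shift of 0.25 fixed for it. Whether macrophage RNA of unchanged makeup was the whole cause stays open. The smallest rise of the 3 genes less its SE was 1.73, above that interval. It lay within the interval of the list's 7 members 1 log2 unit above the median gene (0.323 to 1.85, median 0.42). Those members include Chil3 itself and Ccr2, also a receptor of effector T cells, whose rise of 1.85 is the upper end. The interval of the 7 members therefore cannot decide the question. Other leukocytes also express members such as Lyz2 (0.42) and Ctss (0.32). In both groups the list's median level was highest in replicate 3 (7.85 in PBS, 7.97 in HDM), where Retnla, Chil3 and Mmp12 were lowest. That contrast rests on 1 array per group and does not settle the question, as those arrays differed in the signal of other cells too. Eosinophil, mast cell or basophil RNA stays open too: the median of that list, 0.085 (−0.083 to 0.219), lay below 0.25, but the bound was wrong for a list near the floor (median level below the 6.89 of all genes, with 0 of 14 members 1 log2 unit above that), and Ccr3, a member, rose. Alternatively activated macrophages or expression by the T cells themselves may also account for the rise, which was not tested.

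Endothelial and stromal genes were lower in HDM as a list (camera with the preset correlation only), although the gate took CD45+ cells. A loss of RNA from all non-immune lung cells alike would need a shift of −0.25 in the epithelial list. The median of that list was 0.0688 (95% bootstrap interval −0.159 to 0.207), at a median level of 7.40 against 7.36 for the endothelial list. The whole interval lay above that shift, which argues against such a loss over the 16 epithelial genes as a set. A check chosen after the values were seen took the list's 6 members 1 log2 unit above the median gene. They had a median of −0.03 and a wide interval that held −0.25 (−0.361 to 0.511), so for these members such a loss stays open. Less endothelial and stromal RNA could account for the pattern, with medians of −0.31, −0.62 and −0.39 in the 3 pairs and 7 of 16 genes lower with the block, but stays open because the interval of the list median (−0.417, from −0.756 to −0.227) spans the shift of −0.25 fixed for it. Pecam1, the endothelial list's called gene, is also expressed by naive T cells. A biological difference in endothelial cells of treated lungs was not tested.

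The raised Th2 genes differed less between the arrays numbered 3 than between the others, with a median ratio of the third difference to the mean of the first 2 of 0.803 and with 8 of 10 genes below 1. Dilution of T cell RNA by other cells could contribute, since the ratio of the 345 lowered genes was 0.704 (291 below 1) and the arrays numbered 3 had more B cell, neutrophil and endothelial signal, while that of 21 other raised T cell genes was 1.19 (95% bootstrap interval 0.976 to 1.30). T cell genes themselves lay little lower in these arrays. The 15 T cell receptor genes differed from the other 4 arrays by a median of −0.08, with 4 higher. Cd4 lay at 12.50 in PBS replicate 3 and 12.73 in HDM replicate 3, against 12.47 to 12.71 in the others. A weaker response of all raised genes stays open too, since the 521 raised genes outside the Th2 list had a ratio of 0.933 (0.901 to 0.964), below 1 and above 0.803. These genes were chosen by the test on the same arrays, so their ratios cannot settle either explanation. A permutation of genes between the 10 raised Th2 genes and the 21 others gave p = 0.012 for the difference of their median ratios. It treats genes of the same arrays as independent, so it does not settle whether the type 2 response was weaker in HDM replicate 3. In addition, 1 array per group cannot separate mice from handling.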
